A study of Mus musculus with 8 samples.

How the data were processed

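RNA was measured by poly-A RNA sequencing in 8 libraries of the mouse hepatoma line Hepa 1-6, 4 from cells in which the gene of the histone methyltransferase G9a was knocked out and 4 from wild-type cells. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a SMARTer mRNA kit. The submitters' processing notes name FastQC, Trimmomatic, HISAT2 and the mouse assembly GRCm38.p6. They give no version or role. The counting tool, its use of strand and the annotation release are not given in the sources used here.

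The deposited table held whole-number estimated counts per transcript, not normalized, as its values show, with group names above the library names per the file headers. All 8 value columns belonged to the 8 samples. It listed 115220 transcripts, of which 114332 (99.23%) matched an identifier in GENCODE mouse release 21, an annotation of GRCm38. The 888 unmatched transcripts held between 0.148% and 0.17% of the counts of a library and were left out. The design fixed beforehand had assumed counts per gene. Transcript counts were therefore summed per gene, which gave 47434 genes. Counts of single transcripts were less repeatable than their sums: among 2275 genes with at least 2 transcripts at a mean of 500 or more counts, the median coefficient of variation over the 4 wild-type libraries was 25.4% per transcript and 5.9% for the sum. Coordinates and gene types came from the same annotation. Reads of near-identical copies, such as MHC class I and protocadherin genes, and of overlapping or antisense genes could have been assigned to either gene, so their values are uncertain. Whole counts needed no rounding.

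Library totals lay between 58256100 and 75025236 counts. A count of 0 in 1 library allows a level of up to 3 counts, which is 0.04 to 0.0515 CPM (counts scaled to a library total of 1e6). Such limits and intervals cover counting error alone, because reads without molecular identifiers are not independent molecules. Libraries of a group differed by more than sampling noise (chi-square per degree of freedom of at least 12.52), which does not tell separate cultures from repeated library preparation. Each library was entered as 1 replicate.

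Knockout and wild type were compared with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr, genotype as the only term and Benjamini-Hochberg adjustment over all genes tested. The test was two-sided. Log2 fold changes are knockout minus wild type, and their standard errors (SE) were the size of the log2 fold change divided by the square root of F. CPM values are TMM-normalized, except where they are given as CPM of the library total. A gene "rose" or "fell" when its adjusted p was under 0.05. The genes named were Ehmt2, Ehmt1 and Cxcl10; the 8 largest rises and the 8 largest falls among called genes with at least 10 CPM in the higher group, no overlap between the groups and an official name; and, of each gene list described, up to 4 members with the lowest p, or up to 8 for chemokines, interferon-stimulated genes and MHC class I presentation. Not all genes that this rule selects are described, and 1 of them is not reported here. Other genes are marked as chosen after their values were seen.

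The 53 gene lists, tested with camera of limma 3.58.1 at a preset correlation of 0.01, covered immune, interferon, chromatin, hepatocyte, metabolic, stress, growth and other cell type genes. Camera with a correlation estimated per list and fry were run beside it. The design, the lists and the first set of alternatives (DESeq2 1.42.0, limma-voom, 3 other scalings, 2 other filters, a replicate block, each library left out, a test against 1.5-fold) were fixed before the data were examined. The 4 alternatives on gene position were added later.

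Stretches of chromosomes with a shared shift were sought by binary segmentation of the log2 fold changes, limited to 1 either way, of the 9942 genes with a mean of at least 5 CPM on the autosomes and X. A break was accepted when its gain exceeded the largest in 100 shuffles of gene order and left at least 15 genes on each side. A stretch counted as shifted when its median passed 0.2 either way.

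The code was tested on data simulated for this comparison, in which 200 of 15453 genes were changed. All of these had a mean over 1 CPM, and equally many were raised and lowered. The edgeR test recovered 86.6% of 1.5-fold, 92.5% of 2-fold and 100% of 4-fold changes, and 15 of its 201 calls (7.46%) were false. The share of false calls was 17.7% with DESeq2 and 6.97% with limma-voom. These rates may not carry over to the real comparison, which called 7476 of 15840 genes. Its 2-fold changes were mostly rises (1250 against 374), and 773 of the 1250 were under 1 CPM in the wild type. Such an imbalance and such weakly expressed genes were not simulated. Small values were compared with exact permutation tests, whose smallest two-sided p for 4 against 4 is 0.0286. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and figures. No sequence reads were analysed here.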

Results

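Poly-A RNA of Hepa 1-6, a cell line derived from a mouse hepatoma, was sequenced in 8 libraries. There were 4 libraries of cells with a knockout of G9a, the enzyme encoded by Ehmt2 that places mono- and dimethyl marks on lysine 9 of histone H3, and 4 libraries of wild-type cells. The labels do not say whether libraries of a group came from separate cultures or clones, so p-values measure the spread between these samples, which may be technical. Totals were between 58256100 and 75025236 counts. The knockout libraries held 16229 ± 250 genes with at least 10 counts (SD, n = 4) against 15392 ± 147 in the wild type (exact permutation test, two-sided, p = 0.0286, the smallest this design allows). Mitochondrial transcripts took 3.24% ± 0.18 and 3.29% ± 0.29 of the counts. Pearson correlations of log CPM were between 0.9826 and 0.9875 within a group and between 0.957 and 0.9596 across groups. The first principal component held 82.2% of the variance and separated the genotypes.

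The comparison asked what the loss of G9a does to the transcriptome of these cells, with Cxcl10 and genes of anti-tumor immunity named as the subject by the series title. The targeted gene was checked first. Ehmt2 (ENSMUSG00000013787, chromosome 17, 34898469 to 34914052, GRCm38) was lower in each knockout library. Its levels there were 116.7, 116.7, 119.8 and 118.8 CPM, against 345.4, 307.1, 297.6 and 306.6 CPM in the wild-type libraries. The log2 fold change was -1.41 ± 0.05 (SE, n = 4 per group; edgeR, adjusted p = 3.82e-10). The table has no exon counts, so the position of the lesion was not visible, and the remaining Ehmt2 RNA is not a measure of remaining protein. Ehmt1, whose product forms a complex with G9a, was slightly lower, at 70.7 ± 3.47 against 83.1 ± 2.13 CPM (log2 fold change -0.23 ± 0.05, adjusted p = 0.00157).

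Cxcl10 (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889), a chemokine that attracts T cells through CXCR3, rose from 1.02 ± 0.40 to 4.34 ± 0.69 CPM. Its log2 fold change was 2.09 ± 0.25 (adjusted p = 1.32e-05), and each knockout library (3.74 to 5.15 CPM) lay above each wild-type library (0.64 to 1.56 CPM). The gene stayed at a low level in both groups. It was 1 of 15 chemokine genes that rose among 18 tested, while none fell (edgeR). Adjusted over the list alone, 16 rose. Ccl2, which recruits monocytes, went from 37.9 ± 1.49 to 104.8 ± 7.58 CPM, and its neighbor Ccl7 from 1.05 ± 0.32 to 25.9 ± 4.25 CPM. The neutrophil attractants Cxcl1 and Cxcl5 rose by 2.88 ± 0.12 and 4.70 ± 0.37 on the log2 scale. Pf4 was almost absent from the wild type (0.025 ± 0.051 CPM) and reached 7.75 ± 1.67 CPM. Ccl20 and Cx3cl1 rose by 1.75 ± 0.15 and 0.45 ± 0.05. As a list, chemokines stood above other genes (camera, adjusted p = 6.37e-12; adjusted p = 0.00763 with an estimated correlation). Of the 18, 6 lie on chromosome 5, whose genes as a whole were higher in the knockout (described below).

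**Figure D1:**
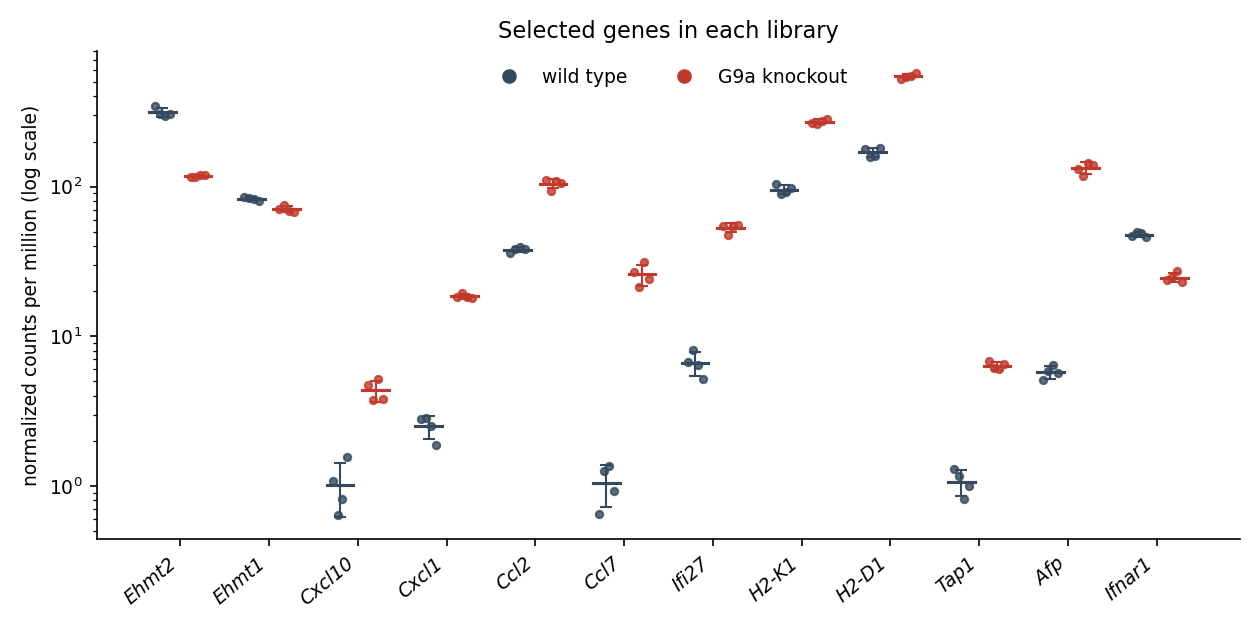
Normalized CPM (log axis) of 12 genes in each library. Dots are libraries, horizontal bars are group means and error bars are SD (n = 4 per group). Ehmt2 is lower in the knockout, from 314.2 to 118 CPM on average, and Cxcl10 is higher in each knockout library than in each wild-type library.

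Interferon-stimulated genes rose together. Of 41 tested, 29 rose, 2 fell and 10 did not pass (adjusted over the list alone, 30 rose and 2 fell). Trim30a, a brake on innate immune signaling, showed the largest rise among genes with at least 10 CPM in the higher group, from 0.031 ± 0.036 to 12.7 ± 0.87 CPM. Ifi27 rose from 6.62 ± 1.21 to 53.1 ± 3.69 CPM. Parp9 and Parp14 rose by 1.80 ± 0.11 and 2.92 ± 0.20 on the log2 scale, Herc6 by 1.67 ± 0.11, Ifit2 by 1.82 ± 0.13 and Lgals3bp by 1.60 ± 0.10. The list passed (camera, adjusted p = 2.97e-12; adjusted p = 0.00763 with an estimated correlation). Interferon-gamma response GTPases, which act on intracellular pathogens, went the same way: 10 of 12 rose and 1 fell (adjusted p = 6.08e-06; adjusted p = 0.0267 with an estimated correlation). Irgm1 and Irgm2 rose by 1.18 ± 0.11 and 3.23 ± 0.30. Gbp4 had 3 counts over the 4 wild-type libraries and 1425 over the knockout libraries, a ratio of 470 with a 95% counting interval of 160 to 2282. It overlaps Gbp9 (log2 fold change 7.75 ± 0.50), so reads of these genes may be shared. The size for Gbp9 is uncertain: it was 10.971 without wild-type replicate 2, the only wild-type library with counts of that gene. Most of these GTPase genes are weakly expressed, and with a filter of at least 5 CPM the list no longer passed (adjusted p = 0.639).

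Genes of MHC class I antigen presentation also rose, 21 of 25, while 1 fell and 3 did not pass (camera, adjusted p = 3.75e-20; adjusted p = 0.009 with an estimated correlation; the same counts adjusted over the list alone). The classical heavy chain genes H2-K1 and H2-D1 went from 95.6 ± 6.92 to 271.9 ± 10.2 and from 169.6 ± 11.8 to 547.2 ± 20 CPM. H2-Q4 rose by 3.83 ± 0.09 and H2-T22 by 1.04 ± 0.05 on the log2 scale, and reads of these related genes may be shared. The peptide transporter genes Tap1 and Tap2 rose by 2.58 ± 0.16 and 3.05 ± 0.17, Tapbp by 0.73 ± 0.04, and Nlrc5, the transactivator of MHC class I genes, by 3.5 ± 0.10. Of 4 tested MHC class II genes 2 rose and 1 fell (camera, adjusted p = 0.771). Ciita, their transactivator, rose from 0.019 ± 0.038 to only 0.35 ± 0.15 CPM (adjusted p = 0.00231).

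Receptors and sensors of these pathways moved in both directions. Among 23 interferon receptor and JAK-STAT genes, 8 rose and 7 fell (adjusted p = 0.832; adjusted over the list alone, 10 rose and 8 fell). Ifnar1, a chain of the type I interferon receptor, fell from 47.8 ± 1.66 to 24.7 ± 1.80 CPM, Il10rb fell by 1.34 on the log2 scale, and Socs2 fell by 1.54. Of 22 nucleic acid sensing genes, 7 rose and 7 fell (adjusted p = 0.727; 8 and 7 adjusted over the list alone): Ddx58 (RIG-I) rose by 0.90 ± 0.07 and Tlr3 from 1.31 ± 0.25 to 5.61 ± 0.86 CPM, while Traf6 was lower (-0.74 ± 0.07). Ifnar1, Il10rb and Traf6 lie in stretches of chromosomes 16 and 2 whose genes shifted together (described below), and lost their call with these shifts taken out (0.157, -0.229 and -0.166). Of 14 immune checkpoint and NK ligand genes 8 rose and 4 fell (adjusted p = 0.589). Cd47 and Cd276 rose by 0.60 ± 0.06 and 0.54 ± 0.04, and Pvr and Nt5e were lower (-0.72 ± 0.05 and -1.77 ± 0.14). NF-kB targets and inflammatory cytokines rose in 12 of 22 cases and fell in 3 (adjusted p = 0.000841; adjusted p = 0.0787 with an estimated correlation). Csf1, the macrophage growth factor, rose from 49.7 ± 3.22 to 146.2 ± 1.93 CPM and the adhesion molecule Vcam1 from 5.71 ± 0.63 to 29.2 ± 1.78 CPM.

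Markers of other cell types were listed because a cell line should lack them. Fibroblast and stellate cell markers rose, 7 of 10 with none falling (camera, adjusted p = 2.63e-05; adjusted p = 0.0453 with an estimated correlation; 7 and 1 adjusted over the list alone). Col3a1 went from 106.8 ± 4.83 to 428.6 ± 12.9 CPM, Col1a2 from 0.44 ± 0.26 to 5.35 ± 0.59 and Des from 2.37 ± 0.14 to 7.93 ± 1.03 CPM. Pdpn was at 154.7 ± 6.86 against 116 ± 3.23 CPM. Extracellular matrix and adhesion genes rose in 22 of 32 cases and fell in 5 (adjusted p = 4.21e-08; adjusted p = 0.26 with an estimated correlation), with Col4a5 up by 1.48 ± 0.06, Col6a1 by 1.34 ± 0.09 and Sparc by 0.84 ± 0.05. Macrophage and myeloid markers (3 of 7 rose, 2 fell, adjusted p = 0.663; 4 and 2 adjusted over the list alone) and endothelial markers (2 of 9 rose, none fell, adjusted p = 0.663) did not pass as lists. T cell and B cell markers had 1 tested gene each, Lck (1.71 ± 0.47 against 1.53 ± 0.34 CPM; list adjusted p = 0.947) and Cd79a (0.34 ± 0.10 against 0.22 ± 0.11 CPM; list adjusted p = 0.838). Neither changed past the threshold.

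Genes of the integrated stress response fell in 21 of 26 cases and none rose (camera, adjusted p = 7.92e-10; adjusted p = 0.0343 with an estimated correlation). Its transcription factor Atf4 went from 473.2 ± 15.8 to 328.1 ± 13.2 CPM, and its targets Trib3 and Chac1 from 33.6 ± 1.49 to 10.7 ± 1.01 and from 18.4 ± 1.63 to 4.18 ± 0.56 CPM (both on chromosome 2; log2 fold changes of -1.65 and -2.14, and -1.077 and -1.561 with the shift of their stretch taken out). The cystine transporter gene Slc7a11 fell from 41.8 ± 4.02 to 13.8 ± 0.25 CPM. Heat shock genes fell in 12 of 16 cases and none rose (adjusted p = 2.45e-05; adjusted p = 0.0798 with an estimated correlation), with Hspa1b at 1.72 ± 0.49 against 23.7 ± 2.25 CPM and Hsp90ab1 at 5726 ± 182 against 7426 ± 254 CPM; Hspa1a and Hspa1b are near-identical copies. NRF2 and oxidative stress genes fell in 18 of 27 cases and 3 rose (adjusted p = 2.38e-06; adjusted p = 0.156 with an estimated correlation). Immediate early genes fell in 18 of 25 cases and 2 rose (adjusted p = 6.42e-05; adjusted p = 0.26 with an estimated correlation; 2 and 19 adjusted over the list alone), among them Nr4a1 (-1.20 ± 0.06) and Dusp5 (-0.90 ± 0.05). Serine and glycine synthesis genes fell in 17 of 21 cases and 2 rose (adjusted p = 0.000841; adjusted p = 0.05 with an estimated correlation), Shmt2 by 0.55 ± 0.04.

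Among chromatin lists, the H3K9 methylation machinery fell in 15 of 25 cases and none rose (adjusted p = 0.00177; adjusted p = 0.26 with an estimated correlation). The list includes the targeted gene Ehmt2 and was not tested without it. Besides Ehmt2, Dnmt3b was lower (-1.04 ± 0.11; -0.468 with the shift of its stretch of chromosome 2 taken out), and Trim28 and Setdb1, partners in silencing by zinc finger proteins, were each lower by a log2 fold change of -0.30. The list of KRAB and other C2H2 zinc finger proteins fell in 102 of 310 cases and rose in 23 (adjusted p = 0.00435; adjusted p = 0.362 with an estimated correlation; 97 and 20 adjusted over the list alone). Zfp991 and Zfp992, members of a local repeat family whose reads may be shared, were lower by -3.70 ± 0.14 and -3.91 ± 0.20. Imprinted genes moved both ways, with 7 of 24 up and 6 down. Their median was 0.011, their mean -0.157 and the test pointed down (adjusted p = 0.0276; adjusted p = 0.136 with an estimated correlation). Grb10, an inhibitor of insulin receptor signaling, fell from 136.8 ± 9.93 to 1.23 ± 0.22 CPM, and Cdkn1c and Phlda2 were also lower (-2.45 ± 0.17 and -1.37 ± 0.07).

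Complement genes rose in 10 of 17 cases and fell in 1 (adjusted p = 0.000249; adjusted p = 0.0787 with an estimated correlation). Clu rose from 83.4 ± 3.94 to 299.5 ± 7.69 CPM, and C1s1 by 3.5 ± 0.27 on the log2 scale. TGF-beta signaling genes had 8 of 22 up and 5 down (adjusted p = 0.0311; adjusted p = 0.183 with an estimated correlation), led by Tgfb3 (1.48 ± 0.07) and Tgfbr3 (1.24 ± 0.06). Both lie in raised stretches of chromosomes 12 and 5; with the shifts taken out they stood at 0.932 and 0.913, and the list was not called (adjusted p = 0.0897). Fatty acid synthesis genes fell in 13 of 21 cases and 3 rose (adjusted p = 0.0151; adjusted p = 0.298 with an estimated correlation; 3 and 14 adjusted over the list alone), with Scd2 at 1211 ± 52.8 against 1638 ± 46.9 CPM. Cholesterol synthesis genes fell in 15 of 25 cases and 3 rose (adjusted p = 0.033; adjusted p = 0.26 with an estimated correlation; 4 up and 15 down adjusted over the list alone), Hmgcs1 by 0.39 ± 0.04. G2/M genes fell in 19 of 36 cases and 6 rose (adjusted p = 0.0311; adjusted p = 0.505 with an estimated correlation). Aurka and Cdc25b, both on chromosome 2, were lower (-0.81 ± 0.04 and -0.75 ± 0.05; -0.233 and -0.175 with the shift of their stretch taken out). Cytosolic ribosomal protein genes fell in 36 of 74 cases and 5 rose (adjusted p = 0.0151; adjusted p = 0.794 with an estimated correlation; 5 and 37 adjusted over the list alone). With library sizes alone as the scaling, the cholesterol, G2/M and ribosomal lists kept their direction and lost their call (adjusted p = 0.101, 0.133 and 0.059). With a filter of at least 5 CPM these and the fatty acid list were not called (0.219, 0.212, 0.139 and 0.0612), and with limma-voom the TGF-beta and imprinted lists were not (0.284 and 0.72).

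**Figure D2:**
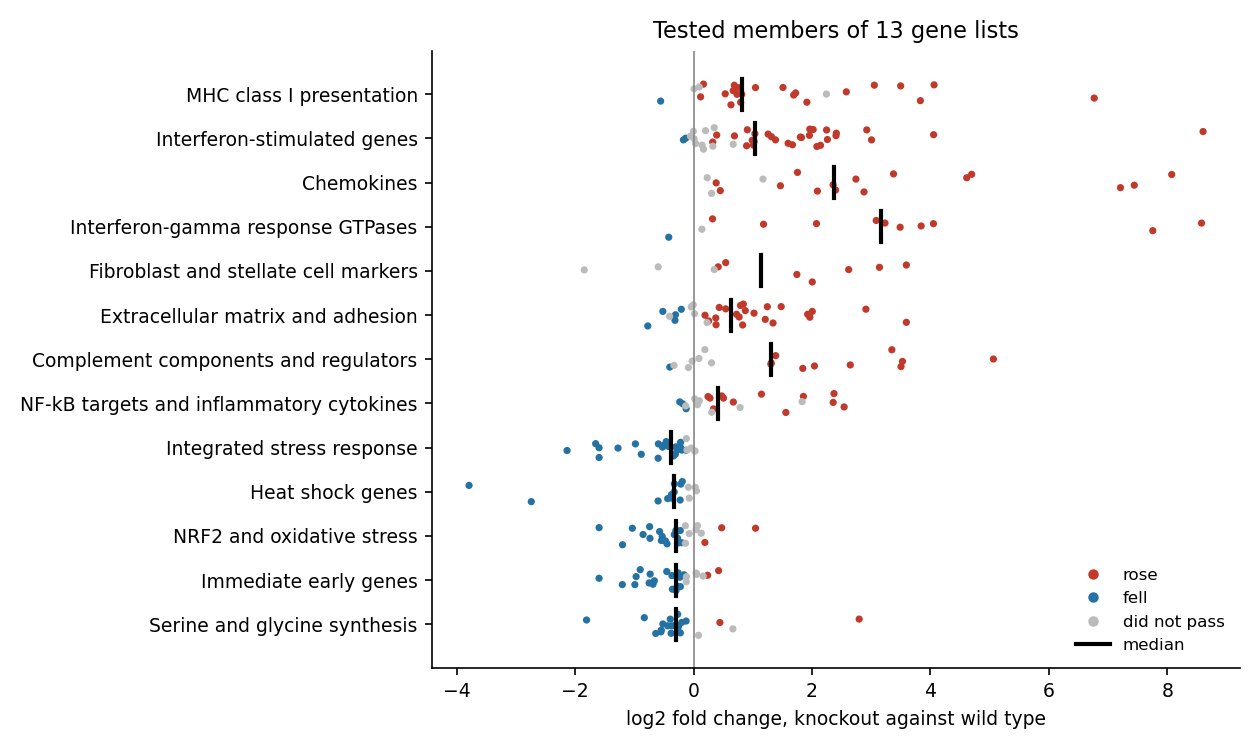
Log2 fold change (knockout against wild type, horizontal axis) of each tested member of 13 gene lists (vertical axis). Red dots rose, blue dots fell, gray dots did not pass an adjusted p under 0.05, and black bars are medians. Medians run from 3.16 for interferon-gamma response GTPases to -0.38 for the integrated stress response.

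Over the whole transcriptome, 7476 of 15840 tested genes passed an adjusted p under 0.05, 3742 higher and 3734 lower in the knockout. With library sizes alone as the scaling, the split was 4543 higher and 2742 lower. Among the 1624 genes that also changed at least 2-fold, 1250 were higher and 374 lower. Of all tested genes 43.9% had no overlap between the groups, against 2.86% by chance. Besides Trim30a, Ccl7 and Afp, the largest rises were those of Tcp11x2 (11.9 ± 0.93 against 0.053 ± 0.106 CPM), Serpinb7 (26.2 ± 1.28 against 0.66 ± 0.18), Ifi209 (13.3 ± 1.46 against 0.51 ± 0.34), Plce1 (13.1 ± 0.59 against 0.54 ± 0.18) and Akr1c13 (15.5 ± 1.34 against 0.69 ± 0.20 CPM). Besides Grb10 and Hspa1b, the largest falls were those of the transporter genes Slco4a1 (0.25 ± 0.17 against 31.3 ± 2.09 CPM) and Slc43a3 (0.27 ± 0.18 against 21.4 ± 1.91), the creatine kinase gene Ckb (0.14 ± 0.12 against 14.2 ± 0.39), Arl6ip1 (1.74 ± 0.36 against 70.4 ± 2.56), the intestinal transcription factor gene Cdx2 (0.69 ± 0.33 against 13.1 ± 1.28) and Stk39 (1.96 ± 0.85 against 32.8 ± 2.31 CPM).

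Liver genes were sparse in both groups. Only 10 of 52 hepatocyte secreted protein genes could be tested; 3 rose and 2 fell (camera, adjusted p = 0.589). Albumin, normally the most abundant hepatocyte transcript and chosen here after its values were seen, had 0 counts in all 8 libraries, which allows at most 0.04 to 0.0515 CPM per library. The oncofetal gene Afp was present and rose from 5.77 ± 0.57 to 133.3 ± 11.9 CPM (log2 fold change 4.53 ± 0.09, adjusted p = 2.12e-12). Of 18 fetal liver and liver cancer genes 5 rose and 10 fell (adjusted p = 0.832), and the test pointed up with library sizes alone. Hepatocyte transcription factors fell in 5 of 16 cases and 1 rose (adjusted p = 0.239), with Cebpb at 56.5 ± 7.36 against 123.3 ± 6.53 CPM (log2 fold change -1.13 ± 0.08; -0.551 with the shift of its stretch of chromosome 2 taken out).

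With fry, 43 of the 53 lists passed an adjusted p under 0.05. Some of them were not called by camera, such as apoptosis regulators (fry, adjusted p = 1.31e-06) and p53 targets (fry, adjusted p = 0.000201). Fry asks whether the members of a list change as a group, without regard to other genes, whereas camera compares them with the other genes. Since 7476 of 15840 tested genes were called, a pass with fry alone does not set a list apart. The lists not described above did not pass the main test, camera. Of these, nuclear retained RNAs passed as lower with all genes with at least 1 read (adjusted p = 0.0357) and with limma-voom (0.0386), and p53 targets passed as lower with all genes with at least 1 read (0.0427). Their counts of rises and falls among tested genes were 6 and 0 of 11 for bile acid synthesis and transport (camera, adjusted p = 0.169), 5 and 3 of 10 for drug metabolism (0.768), 6 and 10 of 21 for the urea cycle and amino acid breakdown (0.815), 3 and 2 of 5 for gluconeogenesis (0.815), 6 and 12 of 24 for glycolysis (0.462), 3 and 8 of 22 for fatty acid oxidation (0.589) and 4 and 11 of 22 for the hypoxia response (0.284). They were 7 and 13 of 29 for p53 targets (0.166), 10 and 8 of 31 for apoptosis regulators (0.663), 8 and 14 of 43 for G1/S and DNA replication (0.315), 10 and 5 of 22 for the unfolded protein response (0.815), 15 and 6 of 31 for autophagy and lysosome (0.815), 5 and 9 of 23 for the Wnt pathway (0.815) and 8 and 7 of 25 for epithelial and mesenchymal genes (0.815). They were 7 and 5 of 23 for Polycomb complexes (0.815), 12 and 3 of 65 for histone genes (0.589), 4 and 0 of 10 for germline genes (0.301), 2 and 0 of 4 for Mage and other X-linked germline genes (0.177), 4 and 1 of 27 for clustered protocadherins (0.832), 0 and 4 of 6 for nuclear retained RNAs (0.103) and 5 and 2 of 13 for mitochondrially encoded genes (0.838). Adjusted over the list alone, the counts differed for the urea cycle (7 and 10), glycolysis (6 and 13), G1/S (8 and 15), Polycomb (7 and 6), histones (11 and 3) and protocadherins (2 and 1). For some of these lists median, mean and test differ in sign: the median and mean were -0.118 and 0.21 for the urea cycle (test down), -0.119 and 0.151 for Wnt (down), -0.03 and 0.077 for Polycomb (down), -0.019 and -0.143 for epithelial and mesenchymal genes (up) and 0.142 and -0.046 for interferon receptors (up). Single members still changed strongly. Ccnd2, a G1 cyclin, fell from 98.8 ± 1.09 to 24 ± 1.36 CPM, S100a4 rose from 150 ± 27.4 to 604.2 ± 51.3 CPM, and the germline RNA export gene Nxf3 had 0 counts over the wild-type libraries and 362 over the knockout libraries, at least 119-fold higher against a floor of 3 counts over the group.

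Fold changes also followed position on the chromosomes. In 5 stretches nearly all genes shared a shift, and each was seen in each of the 4 knockout libraries. On chromosome 2 from 37.4 to 181.9 Mb (GRCm38), 570 of 620 genes with at least 5 CPM were lower, with a median log2 fold change of -0.58. On chromosome 5 from 14.0 to 151.7 Mb, 558 of 624 were higher (median 0.33). This stretch holds Cxcl10, Cxcl1, Cxcl5, Pf4, Afp, Gbp4 and Gbp9. Of the 12 tested interferon-gamma response GTPase genes, only Gbp4 and Gbp9 lie on chromosome 5. On chromosome 12 from 85.3 to 108.5 Mb, 65 of 67 were higher (median 0.55), and on chromosome 8 from 22.1 to 25.6 Mb, 22 of 22 (median 0.46). On chromosome 16 from 84.8 to 92.5 Mb, 32 of 32 were lower (median -1.11), Ifnar1 and Il10rb among them. The interferon receptor genes Ifnar2 and Ifngr2, chosen after their values were seen, lie there too, at -1.131 and -0.897. The end at 92.5 Mb is approximate, since a break had to leave at least 15 genes on each side. Beyond it Runx1 stood at -0.281, but Dop1b, Morc3 and Chaf1b at 93.8 to 93.9 Mb stood at -1.413, -1.47 and -1.183. Hlcs, which follows them, was at -0.091. Genes beyond the end were not adjusted when the shifts were taken out. With the shifts of these stretches taken out, an alternative chosen after seeing the data, Cxcl10 kept a log2 fold change of 1.76 (adjusted p = 7.31e-05), the chemokine, interferon-stimulated and MHC class I lists passed, and Ifnar1, Il10rb and Traf6 were not called (adjusted p = 0.0557, 0.124 and 0.0536). Besides the TGF-beta list, the G2/M and imprinted lists no longer passed (adjusted p = 0.462 and 0.0531). Without the genes in these stretches, the fetal liver list passed as lower (adjusted p = 0.00232).

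**Figure D3:**
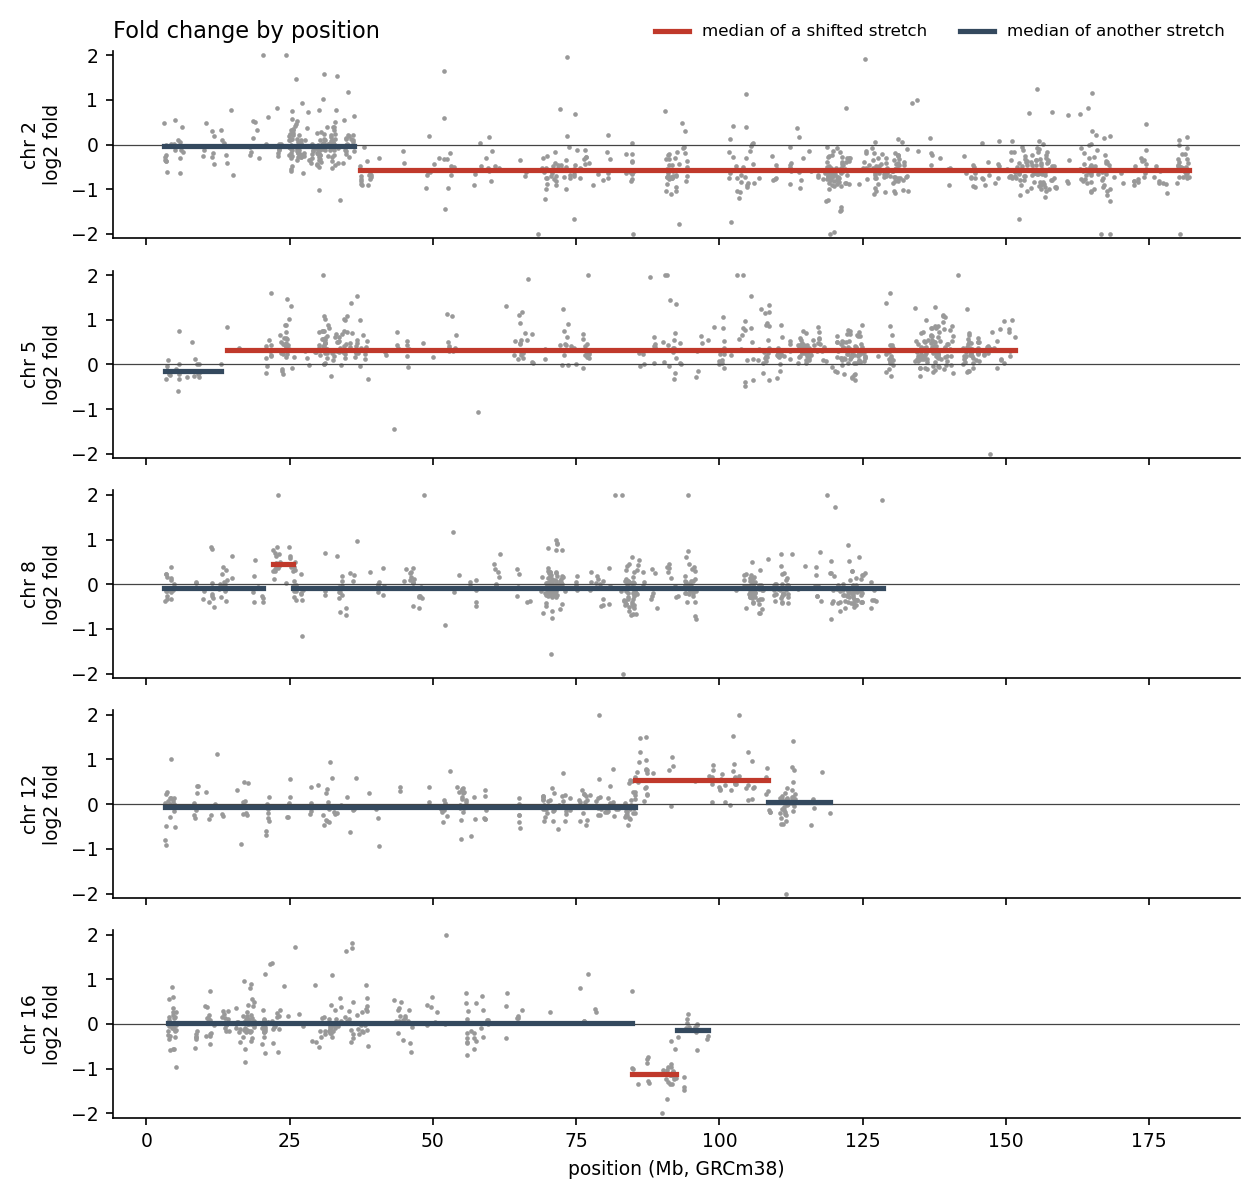
Log2 fold change (knockout against wild type, vertical axis; values past 2 are drawn at 2) of genes with at least 5 CPM against position in Mb (horizontal axis) on 5 chromosomes. Each dot is a gene, red lines are medians of shifted stretches and blue lines those of the rest. The step on chromosome 16 has the largest size, with a median of -1.11 over 32 genes.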

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

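Among 206 groups of 4 values checked for a library far from the other 3 of its group, 11 stood apart, where chance gives about 1 in 20 (10.3). Over all 224 genes selected for naming, 25 of 458 groups did (22.9 by chance), 9 of them through knockout replicate 2. In the wild-type libraries, replicate 2 held Tcp11x2 at 0.2119, Gbp9 at 0.06053 and Ciita at 0.07567 CPM where the other 3 had 0, and Nt5e at 5.857 CPM against 6.46 to 6.537. Replicate 3 held Pf4 at 0.1015 CPM against 0 and Cd276 at 76.88 against 78.68 to 79.01, replicate 1 held Gbp4 at 0.04894 against 0, and replicate 4 held Lgals3bp at 6.349 against 8.051 to 8.336 CPM. In the knockout libraries, Chac1 was at 3.353 CPM in replicate 1 (others 4.387 to 4.549), Zfp992 at 0.7509 in replicate 2 (0.4906 to 0.5329) and Hspa1a at 1.11 in replicate 3 (0.7076 to 0.7669).

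The shift of chromosomes 2 and 5 was weighed first; the test for each whole chromosome was chosen after the result was seen. In 15 of 18 windows of 20 Mb the genes followed their chromosome, but before its shifted stretch chromosome 2 had a median of 0.013 over 324 genes (bootstrap limit toward the shift -0.048; -0.087 in the fixed window from 20 to 40 Mb), which argues against a change of that whole chromosome; chromosome 5 stays open, since the 41 genes with a median of -0.1 (limit 0.1) were bounded by a break found in the same values and the fixed window of its first 20 Mb had an interval of -0.205 to 0.395. The shifts held in highly and weakly expressed genes alike (smallest median 0.295 either way). A copy number difference of parts of chromosomes between the lines would give this. How sharp the steps are was not measured. Release of silent genes alone would leave abundant genes unmoved, but the 290 most abundant genes of chromosome 5 had a median of 0.294, and removing the trend on GC content and gene length moved the median of all chromosome 5 genes from 0.37 to 0.377. Only RNA was measured, so a change of regulation over whole domains is not excluded.

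The rise of chemokine, interferon-stimulated and MHC class I genes was weighed next; the tests on chromosome position, on immune cells, on fibroblasts and on the design were chosen after the result was seen, and that on interferon genes before. With chromosome medians taken out Cxcl10 kept a log2 fold change of 1.721, so its rise was larger than the median shift of chromosome 5 (0.37). Taking out a median cannot tell whether changed genes in the shifted stretches affect these genes. Immune cells are an unlikely source, since 10 immune cell transcripts summed to at most 0.767% of the level of 10 chemokines in a knockout library, but 7 of 10 fibroblast and stellate cell markers rose too and such cells stay open, since Col1a1, Col1a2, Col3a1, Dcn and Lum summed to up to 156%, nearly all of it Col3a1, with Dcn and Lum at or near 0. RNA of interferon genes passed 3 counts in 3 of the 4 knockout libraries, with 4, 14, 16 and 0 counts against 4, 0, 3 and 1 in the wild type (exact permutation p = 0.2857), 40 of these 42 from Ifna13, a gene singled out after its values were seen; these counts are too few to decide. The design holds 0 other groups, such as a rescue or another clone, so loss of G9a itself could not be told from other differences between the lines.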

How the results depend on the processing

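Over the alternatives that test against no change, calls ran from 5786 (at least 5 CPM) to 7791 (DESeq2), and no gene called in the main test was called in the opposite direction under those fixed beforehand. The 2-fold count was 465 with the filter of at least 5 CPM against 1624, because weakly expressed genes are not tested there. A test against a change of 1.5-fold called 1656 genes. Of 21 gene lists, 6 were called with an estimated correlation. For imprinted genes and for serine and glycine synthesis the estimates (0 and -0.003) were below the preset 0.01. A higher correlation therefore does not account for the lost calls of these lists. Cxcl10 stayed between 1.72 and 2.37; it could not be tested at 5 CPM. Without 1 library in turn, calls were 6863 to 7659, rises 3462 to 3866, falls 3325 to 3793, 2-fold changes 1600 to 1724, lists 19 to 21, Ehmt2 -1.44 to -1.37 and Cxcl10 1.93 to 2.37.

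With the replicate number as a block, calls were 7255 (1590 at 2-fold, 21 lists). Correlations between libraries of the same number were -0.285, 0.123, 0.215 and 0.104, and not every library correlated best with its own number. The labels do not say whether the numbers pair the samples, and these few values cannot decide it.

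Alternatives on position were added after seeing the data. With chromosome medians taken out, Ehmt1 stood at 0.118 (adjusted p = 0.0674), since it lies in the part of chromosome 2 that did not shift, and Rpl21 at -0.008 (0.919); 4 more of the 224 genes followed lost their call in the same direction and 2 gained one. With the shifted stretches taken out, Ifnar1 stood at 0.157, Pdk1 at 0.129, Pdia3 at 0.019, Pcna at 0.017 and Sod1 at 0.077, none past the threshold, because all lie in lowered stretches; 10 more lost their call in the same direction. Calls were then 6909, 18 lists passed, and 126 calls had the opposite sign.

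Depth limits genes under 0.04 to 0.0515 CPM, which cannot be told from absent.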

Other observations

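Some genes were on in only 1 group. With under 0.1 CPM (of the library total) in each library of a group and over 1 CPM in each library of the other, 13 genes were on only in the knockout and 5 only in the wild type. Of the 2-fold raised genes 773 of 1250 (61.8%) were under 1 CPM in the wild type, and of the 2-fold lowered genes 208 of 374 (55.6%) were under 1 CPM in the knockout. Raised genes lay side by side: 251 neighboring pairs were both raised at least 2-fold, against a median of 101 in 10000 random draws matched on wild-type level (permutation test, p = 0.0001, the smallest possible), with the prediction written before the test was run. In 2 comparisons chosen after that result, among pairs whose names do not share a stem there were 117 against a highest draw of 70, and of these 89 outside the shifted stretches against 62. This is consistent with release of local domains, but the test does not tell that from shared reads or shared regulators.

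Hepatocyte genes at or near 0 in all libraries were weighed, with tests chosen after the result was seen. All 52 members of the secreted protein list were in the table, so missing entries do not account for it, and 25 of them had 0 counts in all 8 libraries. A low share of hepatic cells in a mixed culture would show Alb wherever less abundant members are counted. Alb had 0 counts in all 8 libraries, while Apoa2, Serpinc1, Apoe and Fetub had counts in each (508, 264, 4316 and 6118 in total). This argues against such cells as the source of the RNA of these genes. A share too low to be counted stays open. The sum of Alb, Ttr, Apoa1, Apob, Serpina1b and Fgb was at most 0.351 CPM of the library total, but these genes were picked for being near 0. Among genes chosen after their values were seen, Sox2 was at 45.8 and 45.6 CPM of the library total and Krt8 at 822.7 and 701.3 in knockout and wild type. The identity of the line was not tested, and no biological explanation was tested.

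All 35 divisions of the 8 libraries into 4 and 4 were compared. For genes past the threshold the real division gave 7476 and the highest other 1, and for rises 3742 and 1. For falls it gave 3734 and 1, and for 2-fold changes 1624 and 1, each reached by 1 of 35. Every other division mixes the genotypes, so these counts show only that the groups of libraries differ. A chance difference between separately grown or cloned cells is not excluded, since libraries of a group may share a culture or clone. For the number of gene lists the real division gave 21 and the highest other 21 (2 of 35). For markers of other cell types it gave 1 and 1 (12 of 35), so chance is not excluded for these counts. Divisions that keep 3 of the 4 knockout libraries together still hold part of the difference. The chemokine, interferon-stimulated and MHC class I lists had their smallest p in the real division, 3.61e-13, 1.12e-13 and 7.07e-22 against 6.22e-07, 1.61e-08 and 3.29e-08, each in 1 of 35; this test was added after the list results were seen, with its prediction written before it was run. Of the 21 called lists 11 were reached by the real division alone. Apoptosis regulators and nucleic acid sensing, which were not called, were also reached by the real division alone (1 of 35). Every other division mixes the genotypes, so this count does not exclude chance for the 11. Chance is not excluded for the other 10 either. Their p was as small in 22 of 35 divisions for ribosomal proteins, 9 for G2/M and 8 for zinc finger proteins. It was as small in 7 each for cholesterol and fatty acid synthesis, 6 for the H3K9 machinery and 5 for immediate early genes. It was as small in 3 each for complement and serine synthesis and 2 for imprinted genes.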
